A study of Mus musculus with 24 samples.

How the data were processed

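Mouse E14 embryonic stem cells were transfected with an antisense oligonucleotide containing locked nucleic acids (LNA) against tRF-GG, a fragment of glycine tRNAs, with an endoribonuclease-prepared siRNA pool (esiRNA) against GFP as a control, or mock-transfected. From each of these 3 kinds of transfected culture, RNA isolated with Trizol was sequenced (values called mRNA abundance here) and ribosome footprints were measured by sequencing RNAs of 26 to 32 nucleotides recovered from ribosomes after RNase digestion and a sucrose gradient, per the labels' protocols. Each of the 6 groups held 4 libraries, 24 in all, and libraries are named here by group, assay and the number their labels give.

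The deposited values were FPKM per gene, one table for the RNA libraries and one for the footprint libraries, with 23917 gene symbols and 2 decimals. Per the submitters' processing notes, CASAVA 1.8.2, TopHat, Bowtie2 and RSEM were used, with the mm10 mouse genome; the versions of the other programs are not given in the sources used here. Per the file headers the values are RSEM estimates listed with RefSeq transcripts, and RSEM divides reads that match several transcripts among them by an estimate. Which genes this touched was not checked here by sequence. FPKM are relative to the total of each library, so that a library with much ribosomal RNA has lower FPKM for every other gene. Read counts were not used here. Of the gene symbols, 22501 matched a symbol of the RefSeq table for GRCm38.p6, the assembly known as mm10, and 23769 (99.4%) matched a symbol or a synonym; coordinates come from that table.

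Depth was estimated from low values. Where RSEM had assigned whole reads, the lowest steps of a gene's FPKM differ between libraries by their depth, and this gave depth relative to the deepest library of each table. The estimate from library pairs lay within 0.1 (log2) of the fitted depths in 56 of 64 RNA pairs and 61 of 66 footprint pairs. Relative depth ranged from 7.2% to 100% among RNA libraries and from 20.4% to 100% among footprint libraries. Absolute depth is unknown, so no counting intervals are given. No library pair held identical values (0 pairs in each table).

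FPKM were scaled between libraries by a median of ratios over the genes with at least 5 FPKM in every library (1717 genes in the RNA table and 2960 in the footprint table), and log2(scaled FPKM + 1) was taken. Fold changes are on this scale, which understates the change of genes with low values. Genes with a mean of at least 0.5 FPKM were tested, 12560 in RNA and 10669 in footprints. Differences were tested with limma 3.58.1 in R 4.3.3, with a trended, robust empirical Bayes estimate of spread from all 3 groups of a table, two-sided p-values, Benjamini-Hochberg adjustment over the genes tested, and a threshold of 0.05. Translational efficiency, the footprint value over the RNA value of a gene, was tested for 10497 genes as the interaction term of one limma model over all 24 libraries. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 served for the depth estimate, tables and plots.

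A set of 29 gene lists was fixed before the data were examined, together with the tests, the filter, the scaling, the alternatives and the rule for naming genes. The lists cover programmes of early development and pluripotency, other cell types a culture could hold, histones, the translation machinery, stress responses, metabolism, the cell cycle and control of repeats. Of these, 28 had at least 5 measured members and were tested with limma's camera, which compares the members with all other genes, at a preset correlation of 0.01 and with adjustment over the lists. Counts of members past 0.05 are also given adjusted over the list alone. A score per library, the mean of the members' centred log2 values, was compared between groups by a two-sided exact permutation test over the 70 assignments of 8 libraries. For inhibitor and GFP libraries, scores of the 2-cell list, the replication-dependent histones and genes spanning over 200 kb were also tested over pairs, in RNA and in footprints. That test takes the 16 sign changes of the differences of 4 numbered pairs and cannot give a p under 0.125. For the 2-cell list, limma's fry, which tests whether the members move one way on balance, was run in the paired fits, with adjustment over the lists; its use was chosen after the result was seen.

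The genes named in the text follow a rule. For the inhibitor against the GFP control, in each of the 3 measures, the rule takes the 8 largest rises and the 8 largest falls among genes past the threshold whose 4 libraries of one group all lie on one side of the other group's mean. It adds the 3 members with the smallest p from each list with a camera adjusted p under 0.05 or with a passing member. For the other comparisons it takes the 3 largest rises and falls past the threshold, and where no gene passes the 3 smallest p in each direction. Genes named from the paired fit below, and the single-copy members of the 2-cell list, were chosen after their values were seen. Genes are called single-copy, or members of a family of similar genes, from general knowledge.

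Groups share replicate numbers in the labels, and nothing in the labels says what a number stands for. Same-numbered libraries were checked by the correlation, across genes with at least 5 FPKM (7224 in RNA and 4463 in footprints), of their deviations from the group means. For RNA, these lay between 0.39 and 0.82 for inhibitor and GFP libraries, between 0.32 and 0.56 for inhibitor and mock, and between 0.38 and 0.70 for GFP and mock. For footprints of inhibitor and GFP libraries they lay between 0.46 and 0.82. All 4 pairs exceeded 0.1 in each of these, the threshold set for treating the numbers as pairs, so a limma fit with the replicate number as a block is given beside those results where it changes them. Footprint libraries of the mock group were not paired with the others by their numbers.

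The tests were tried on simulated data with the real means and spread, in which 100 genes were changed 2-fold and 100 were changed 4-fold. Each simulated gene varied independently of the others. For RNA of inhibitor and GFP groups, 17 of the 2-fold and 66 of the 4-fold changes were called, with 5 unchanged genes called. The paired fit called 28 and 77. The same footprint comparison called 33 and 82, and translational efficiency 9 and 55.

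Alternatives were a pseudocount of 0.1, no filter, a filter at 5 FPKM, FPKM as deposited, quantile normalization, a fit of only the groups compared, the replicate block, each library left out in turn, and camera with an estimated correlation. Further alternatives were added after seeing the data: leaving out the RNA libraries numbered 1, the same with the replicate block, the block in a fit of only the groups compared, and an estimated correlation with the block. The labels do not say whether replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical. tRF-GG itself was not measured in these tables, and no group received an LNA oligonucleotide with another target.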

Results

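RNA and ribosome footprints of mouse E14 embryonic stem cells were measured after 3 kinds of transfection: an LNA oligonucleotide antisense to the glycine tRNA fragment tRF-GG (the tRF-GG inhibitor), an esiRNA against GFP as control, and a mock transfection. Each group held 4 RNA libraries and 4 footprint libraries. The 45S ribosomal precursor Rn45s made up 62.7% of the summed FPKM in the inhibitor RNA library numbered 1, 39.1% in mock RNA 1 and 18.1% in GFP RNA 1, against 1.7% to 5.3% in the other RNA libraries. Its share in footprint libraries ranged from 18.5% to 44.2%. Inhibitor RNA 1 listed 6697 genes at 1 FPKM or more, and the largest number in an RNA library was 11884. Relative depth differed 13.9-fold among RNA libraries, lowest in mock RNA 3, and 4.9-fold among footprint libraries, lowest in inhibitor footprint 3.

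**Figure D1:**
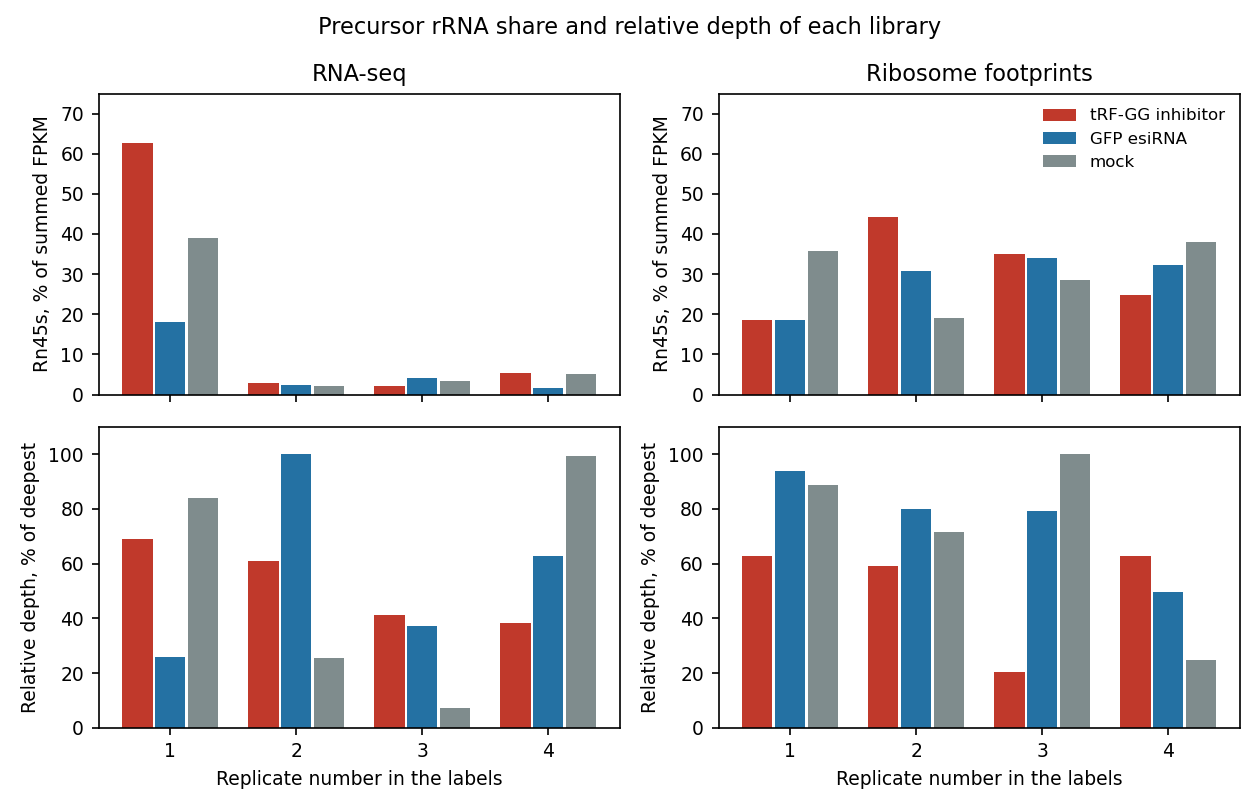
Share of summed FPKM taken by the ribosomal precursor Rn45s (bars, percent) and depth relative to the deepest library of the same table (bars, percent) for each of the 24 libraries, by group and replicate number. The RNA libraries numbered 1 stand at 62.7%, 39.1% and 18.1% Rn45s in the inhibitor, mock and GFP groups.

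The comparison of inhibitor with GFP control RNA asks which mRNAs change when tRF-GG is blocked. Tdpoz4, of a POZ and TRAF domain family active in the early embryo, rose by 3.56 (log2, SE 0.50, n = 4 per group), from 0.257 ± 0.400 to 16.7 ± 12.9 scaled FPKM (SD). Bcas3, a cytoskeleton-associated WD40 protein, decreased by 1.22 (SE 0.17), from 11.6 ± 1.07 to 4.4 ± 0.456 scaled FPKM. In the fit that pairs libraries by replicate number, 29 genes were higher and 3 lower. Those that rose there included Tcstv3 (2.64, paired SE 0.22), Zfp352 (2.57, paired SE 0.38) and the nuclear body gene Sp110 (2.35, paired SE 0.35), all members of the 2-cell list described below. Others that rose were the doublecortin-domain gene Dcdc2c (2.57, paired SE 0.23) and Plet1, a placenta-expressed surface protein (1.63, paired SE 0.22). Plekha5, a PH-domain protein (-1.12, paired SE 0.19), and the receptor phosphatase Ptprg (-0.98, paired SE 0.17) fell there with Bcas3.

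By limma over 12560 genes without pairing, Tdpoz4 and Bcas3 were the 2 genes past the threshold, each with an adjusted p of 0.0324; with the replicate block these were 0.00222 and 0.00727, and 32 genes passed. Over all alternatives the adjusted p ranged from 4.91e-07 to 0.204 for Tdpoz4 and from 0.00727 to 0.914 for Bcas3. Unpaired adjusted p-values were 0.710 for Tcstv3, 0.0983 for Zfp352, 0.0781 for Dcdc2c and Sp110, 0.396 for Plet1, 0.0820 for Plekha5 and 0.420 for Ptprg. Leaving out inhibitor RNA 1 or 3 or any 1 of the 4 GFP libraries left 0 genes by limma, leaving out inhibitor RNA 2 gave 1 other gene (adjusted p = 0.0792 for both Tdpoz4 and Bcas3), and leaving out inhibitor RNA 4 gave 15. In the fits that left 0 genes, Tdpoz4 stood at 3.12 to 3.76 and Bcas3 at -1.27 to -1.17. Leaving out the 3 RNA libraries numbered 1 left 0 genes unpaired and 9 with the block. At an unadjusted p under 0.05 there were 391 genes without and 861 with the block, where chance gives 628. Tdpoz4 lies on chromosome 3 (93796398 to 93797510, GRCm38), and its value is uncertain, as it belongs to a family of similar genes and the division of reads among them was not checked here. Bcas3 lies on chromosome 11 (85353110 to 85826058).

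Genes of the 2-cell embryo, a list that includes the Zscan4, Tcstv, Tdpoz and Usp17l families and genes driven by the MERVL retroelement, were higher in inhibitor RNA. Of 47 measured members 45 had values above 0, with a median of 1.21 (log2, quartiles 0.33 and 1.84). The files held 59 members, and the filter took the mean over all 12 libraries, the inhibitor included. A member near 0 in the controls could therefore be measured through high inhibitor values alone. Such selection favours values above 0, here and in the comparisons below. Over the alternatives, which include no filter, the median ranged from 0.93 to 2.24. One member, Tdpoz4, passed over all genes; adjusted over the list alone 17 members rose, and in the paired fit 13 rose over all genes and 31 over the list alone. The 6 measured members with no near-identical copy by general knowledge were Arg2, the mitochondrial arginase (1.70, SE 0.32, adjusted p = 0.0847 by limma), the growth factor Fgf1 (1.21, SE 0.30, adjusted p = 0.524), Abcb5 (1.20, SE 0.29), Ddit4l (0.88, SE 0.37), Tmem92 (0.22, SE 0.55) and Calcoco2 (0.08, SE 0.60). The list passed camera with an adjusted p of 1.95e-40, and had an adjusted p = 0.356 with an estimated correlation (range over the alternatives 1.36e-122 to 0.356). Its mean score was 0.83 ± 0.88 (SD, n = 4) in inhibitor and -0.41 ± 0.52 in GFP libraries, higher in 4 of 4 numbered pairs by 0.55 to 1.57, with an exact permutation p of 0.0571 where the smallest possible is 0.0286 (adjusted p = 0.914 over the lists). Even at the smallest possible p, a single list could not pass after adjustment over 28 lists, so the adjusted value cannot decide. The list was drawn up with general knowledge that the study concerned such genes, so its direction is not independent of the study. Values of single members of the Zscan4, Tcstv, Tdpoz and Usp17l families are uncertain, as the division of reads among similar copies was not checked here.

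**Figure D2:**
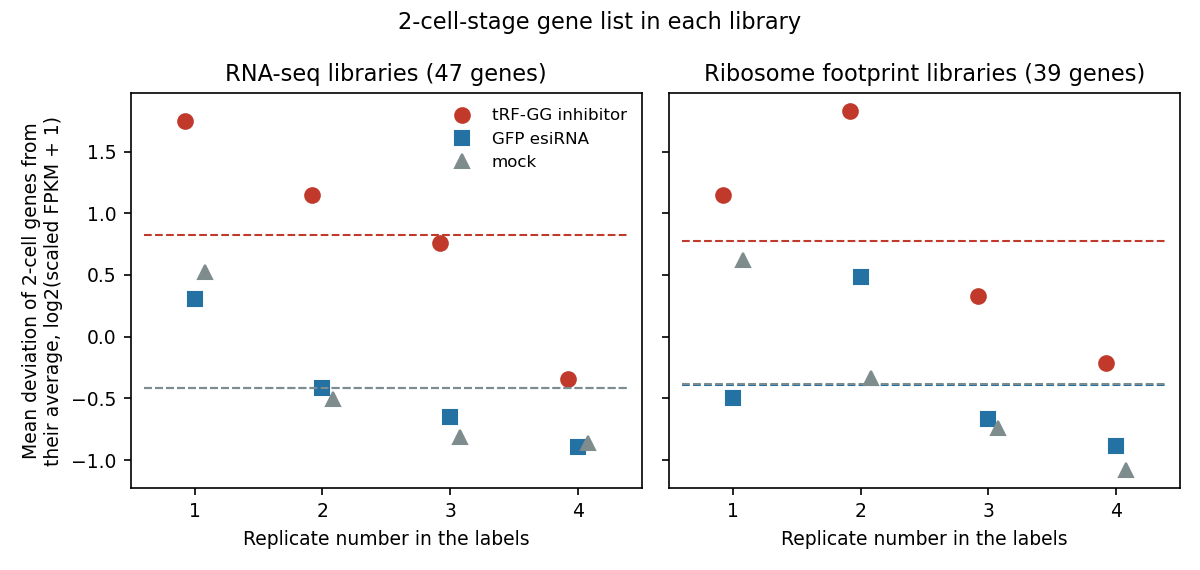
Mean centred log2 value of the 2-cell embryo list (vertical axis) in each RNA library (47 genes) and footprint library (39 genes), by transfection and replicate number; dashed lines are group means. Inhibitor RNA scores average 0.83 and GFP RNA scores -0.41, and the 2 groups overlap where GFP RNA 1 at 0.30 lies above inhibitor RNA 4 at -0.34, which lies above the other 3 GFP libraries.

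Replication-dependent histones were lower in inhibitor RNA than in GFP RNA, with 56 of 64 members below 0 and a median of -0.26. The linker histone Hist1h1e stood at 144 ± 27.6 against 235 ± 49.6 scaled FPKM (-0.70, SE 0.22, n = 4 per group), Hist3h2a at -0.93 and Hist1h2bh at -1.01. No member passed by limma over all genes (0) or adjusted over the list alone (0), and 3 were lower over the list alone in the paired fit. The list's camera adjusted p was 1.04e-06, with an adjusted p = 0.928 with an estimated correlation (range over the alternatives 3.97e-10 to 0.928). Without the RNA libraries numbered 1 the median was -0.04 (adjusted p = 0.499), and without GFP RNA 1 alone it was -0.10 (adjusted p = 0.126). The other 26 lists did not pass (adjusted p from 0.0597 to 0.995). Their medians included 0.04 for fibroblast feeder markers and 0.09 for interferon and nucleic acid sensing. With the block 6 lists passed, the further ones being naive pluripotency (median -0.19, blocked adjusted p = 0.00657, 0.0814 without the block), p53 targets (0.15, 0.00657 and 0.0597), trophoblast genes (0.26, 8 of 8 above 0, 0.0244 and 0.182) and glycolysis and hypoxia genes (-0.14, 0.0379 and 0.244), each with a blocked adjusted p = 0.588 with an estimated correlation.

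The comparison with mock-transfected cells repeats the question against a second control. Sbsn, suprabasin of the epidermis, rose by 2.20 (log2, SE 0.29, n = 4 per group), from 0.0738 ± 0.148 to 4.24 ± 1.94 scaled FPKM. AF067063, a member of the 2-cell list and of a small family of similar genes, rose by 2.32 (SE 0.33), from 0.0390 ± 0.0780 to 4.69 ± 2.60. Bcas3 decreased by 1.24 (SE 0.17), from 11.9 ± 1.83 to 4.4 ± 0.456. In the paired fit 31 genes were higher and 3 lower, among them Tcstv3 (3.11), Tdpoz4 (3.12), Zfp352 (2.73) and Plekha5 (-1.12). The limma adjusted p-values were 0.0226 for Sbsn and Bcas3 and 0.0243 for AF067063 unpaired, and 0.00356, 0.00606 and 0.00373 with the block; over the alternatives they ranged from 0.000780 to 0.131, 0.00606 to 1 and 0.000128 to 0.145. Leaving out inhibitor RNA 1 or 3 or any 1 of the 4 mock libraries left 0 genes, with Sbsn at 2.03 to 2.30, AF067063 at 2.07 to 2.38 and Bcas3 at -1.30 to -1.16 in those fits, and leaving out inhibitor RNA 4 gave 18; without inhibitor RNA 2 AF067063 had an adjusted p of 0.0878. Without the 3 RNA libraries numbered 1 there were 3 genes, of which 0 were among these. By limma 460 genes without and 1057 with the block had an unadjusted p under 0.05, where chance gives 628. Sbsn lies on chromosome 7 (30732674 to 30756134) and AF067063 on chromosome 13 (119827961 to 119830217).

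Against mock, 44 of 47 genes of the 2-cell list had values above 0, with a median of 1.19 and a camera adjusted p of 1.82e-35, and an adjusted p = 0.491 with an estimated correlation (range over the alternatives 1.07e-114 to 0.491). One member passed over all genes and 18 adjusted over the list alone, and with the block 14 and 29 did. Of 64 replication-dependent histones 54 were below 0 (median -0.31, adjusted p = 2.34e-06, and 0.906 with an estimated correlation, range 2.36e-18 to 0.906), and without the RNA libraries numbered 1 the median was -0.15 (adjusted p = 0.160). Cytosolic ribosomal proteins had a median of -0.12 (65 of 83 below 0, adjusted p = 0.0182), p53 targets of 0.15 (18 of 23 above 0, adjusted p = 0.0182) and ATF4 stress response genes of -0.16 (18 of 23 below 0, adjusted p = 0.0298). Each of these 3 had an adjusted p = 0.906 with an estimated correlation. None of the 3 held without the libraries numbered 1, with medians of -0.05, 0.12 and -0.13 (adjusted p = 0.505, 0.136 and 0.136), and quantile normalization put the ribosomal proteins at 0.02 (adjusted p = 0.672). The p53 and ATF4 medians were -0.13 and -0.39 in FPKM as deposited (adjusted p = 0.673 and 0.257), where the median of all genes was -0.19.

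Single libraries also ended these 3 smaller list calls against mock. For ribosomal proteins the camera adjusted p was 0.320 without inhibitor RNA 1, 0.10 without inhibitor RNA 4, 0.106 without mock RNA 1 and 0.746 without mock RNA 3, with medians of -0.03, -0.10, -0.12 and -0.07. For p53 targets it was 0.107 and 0.0650 without inhibitor RNA 1 and 2, and 0.134 and 0.120 without mock RNA 3 and 4, with medians of 0.09, 0.08, 0.08 and 0.13. For ATF4 genes it was 0.320 and 0.193 without inhibitor RNA 1 and 2, and 0.176 and 0.134 without mock RNA 2 and 3, with medians of -0.05, -0.15, -0.12 and -0.16. Over their alternatives these p-values ranged from 4.17e-05 to 0.906, 0.000979 to 0.906 and 0.00524 to 0.906. At the level of single genes none of these lists had a member past the threshold over all genes by limma (0 each), and 1 p53 target passed adjusted over the list alone. The other 23 lists had adjusted p-values from 0.181 to 0.936. With the block 8 lists passed, the further ones being trophoblast genes (median 0.31, blocked adjusted p = 0.00979), immediate early genes (0.21, 0.0160) and glycolysis and hypoxia genes (-0.14, 0.0160), each with a blocked adjusted p = 0.491 with an estimated correlation.

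Between the 2 controls, GFP esiRNA and mock, no mRNA passed. The genes with the smallest p were the retinol dehydrogenase Rdh14 (0.85, SE 0.32), the lipoyltransferase Lipt1 (0.71, SE 0.27) and Tmem45a (0.67, SE 0.25) among those higher, and Taz (-0.76, SE 0.26), 2310039H08Rik (-1.24, SE 0.30) and the pseudogene Rps19-ps3 (-2.09, SE 0.72) among those lower, each with n = 4 per group and a limma adjusted p of 1. The 2-cell list had a median of 0.02 (mean -0.00) and the replication-dependent histones of 0.01 (mean -0.04). Of 12560 genes 0 passed limma with or without the block. An unadjusted p under 0.05 was found for 66 genes without and 200 with the block, where chance gives 628. Both fits are therefore cautious, and a count of 0 does not show equal mRNA in the 2 controls. Of 28 lists 0 passed (adjusted p from 0.763 to 0.946). With the block 2 did, primitive endoderm (median -0.14) and immediate early genes (0.16), each with a blocked adjusted p of 0.0356, and 1 with an estimated correlation.

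In ribosome footprints, the comparison of inhibitor with GFP libraries asks which transcripts gain or lose ribosomes. The snoRNA Rnu73b was listed at 0 in all 4 inhibitor and all 4 mock libraries and stood at 1.81, 3.10, 3.8 and 5.18 scaled FPKM in GFP footprint libraries 1 to 4. A snoRNA is not translated, so these reads do not measure ribosomes on it. Its values are low, and it was not tested at a mean of at least 5 FPKM. In the paired fit, Sp110, a member of the 2-cell list, rose by 2.85 (log2, paired SE 0.32, n = 4 per group), from 0.526 ± 0.406 to 11.8 ± 8.51 scaled FPKM, and Plet1 by 1.43 (paired SE 0.16), from 6.02 ± 2.64 to 17.8 ± 7.53. Igfbp7, a secreted binder of insulin-like growth factors, decreased there by 1.26 (paired SE 0.15), from 4.94 ± 1.47 to 1.45 ± 0.382, as did the nucleolar gene Aatf (-0.91), the vesicle traffic gene Trappc9 (-0.87) and the transcription factor Klf15 (-0.77). By limma over 10669 genes, Rnu73b passed with an adjusted p of 0.000659, and 0.00320 with the block (range over the alternatives 2.02e-05 to 0.0229). With the block 3 genes were higher and 5 lower in the fit that includes the mock libraries, whose numbers did not pair with these groups. With the block and only the 2 groups compared, 45 genes passed, 37 higher and 8 lower, and the adjusted p of each of the former 8 lay between 0.00843 and 0.0449. Adjusted p-values with and without it were 0.0149 and 0.0871 for Sp110, 0.0149 and 0.901 for Plet1, 0.0149 and 0.132 for Igfbp7, 0.0237 and 0.618 for Aatf, 0.0297 and 0.562 for Trappc9, and 0.0309 and 0.510 for Klf15. Without inhibitor footprint 2 the unpaired count was 2 and without inhibitor footprint 4 it was 3; 353 genes without and 826 with the block had an unadjusted p under 0.05, where chance gives 533. Sp110 lies on chromosome 1 (85570735 to 85610850), Plet1 on chromosome 9 (50494525 to 50505639) and Igfbp7 on chromosome 5 (77349240 to 77408045).

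The 2-cell list was also higher in inhibitor footprints, with 34 of 39 members above 0 and a median of 1.10. Adjusted over the list alone 13 members rose and over all genes 0 did by limma; with the block 21 rose and 1 fell over the list alone, and 1 rose over all genes. Zfp352 stood at 2.06, Arg2 at 1.5 (SE 0.36), Tmem92 at 0.37 (SE 0.38) and Calcoco2 at -0.35 (SE 0.31). The camera adjusted p was 6.15e-23, with an adjusted p = 0.446 with an estimated correlation (range over the alternatives 1.42e-53 to 0.446). Scores were 0.77 ± 0.90 in inhibitor and -0.39 ± 0.60 in GFP libraries (SD, n = 4), higher in 4 of 4 pairs by 0.67 to 1.64, with an exact permutation p of 0.0857 unpaired and 0.125, the smallest possible, over the sign changes of the pairs, and the adjusted p of limma's fry in the paired fit was 0.212. Trophoblast markers had a median of 0.42 in the same footprints (4 of 7 above 0, camera adjusted p = 0.638) and fibroblast feeder markers of 0.06 (5 of 9 above 0, adjusted p = 0.496), and their scores were higher in 4 of 4 pairs, by 0.14 to 0.34 and by 0.05 to 0.23 (exact permutation p = 0.486 and 0.400 unpaired). Replication-dependent histones had a median of -0.21, with 52 of 64 below 0 and Hist1h1e at 150 ± 45.3 against 239 ± 44.7 scaled FPKM (adjusted p = 2.63e-06, and 0.834 with an estimated correlation, range 5.56e-16 to 0.834). Their score was lower in 4 of 4 pairs, with differences from -0.26 to -0.06 (exact permutation p = 0.457 unpaired, and 0.125 over the sign changes). Without inhibitor footprint 1 their median was -0.12 (adjusted p = 0.105) and without GFP footprint 3 it was -0.07 (adjusted p = 0.399).

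Another 5 lists passed camera in these footprints. Naive pluripotency genes had a median of -0.12 with 24 of 30 below 0 (adjusted p = 0.0288, and 0.446 with an estimated correlation). Its members with the smallest p were the maternal factor Dppa3, at 0.90 (SE 0.21, adjusted p = 0.515) and higher when adjusted over the list alone, Klf4 (-0.51, SE 0.20) and Socs3, an inhibitor of LIF signalling (-0.56, SE 0.20). Nuclear genes of oxidative phosphorylation had a median of -0.07 (63 of 83 below 0, adjusted p = 0.00649, and 0.834 with an estimated correlation), with Ndufb8 at -0.35, Ndufb9 at -0.40 and Cox4i2 at -0.58. ATF4 genes had a median of -0.07 (18 of 22 below 0, adjusted p = 0.00700, and 0.446 with an estimated correlation), with Cebpb at -0.28, Phgdh at -0.38 and Atf5 at -0.57. Cytosolic ribosomal proteins had a median of -0.06 (62 of 82 below 0, adjusted p = 0.0288, and 0.917 with an estimated correlation), with Rps14 at -0.19, Rpl7a at -0.23 and Rpl41 at -0.34. Targets of p53 had a median of 0.12 (18 of 22 above 0, adjusted p = 0.0391, and 0.834 with an estimated correlation), with Plk2 at 0.53, Perp at 0.42 and Cdkn1a at 0.38.

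None of these 5 calls held without GFP footprint 3, where adjusted p-values were 0.233 for naive pluripotency (median -0.08), 0.846 for oxidative phosphorylation (0.01), 0.156 for ATF4 genes (-0.16), 0.399 for ribosomal proteins (0.02) and 0.154 for p53 targets (0.11). Without inhibitor footprint 2 they were 0.141, 0.289, 0.0684, 0.0809 and 0.372, with medians of -0.09, -0.02, -0.11, -0.06 and 0.08. Without inhibitor footprint 1 the adjusted p was 0.220 for naive pluripotency (median -0.08), 0.0738 for ATF4 genes (-0.09), 0.900 for ribosomal proteins (-0.01) and 0.0667 for p53 targets (0.12). Naive pluripotency was also lost without inhibitor footprint 4 (0.0825, median -0.10) and GFP footprint 4 (0.0567, -0.06), ribosomal proteins without inhibitor footprint 4 (0.119, -0.06), and p53 targets without inhibitor footprint 3 (0.228, 0.15), GFP footprint 1 (0.125, 0.17) and GFP footprint 4 (0.103, 0.14). Over the alternatives the p-values ranged from 0.000555 to 0.446, 3.02e-06 to 0.846, 0.000166 to 0.446, 3.01e-07 to 0.917 and 0.00214 to 0.834. Quantile normalization put the ribosomal proteins at 0.02 (adjusted p = 0.329) and gave an adjusted p of 0.0970 for naive pluripotency (median -0.13) and 0.105 for oxidative phosphorylation (-0.07). The p53 call was lost with no filter (adjusted p = 0.161, median 0.09) and in FPKM as deposited (0.145, 0.05). The other 21 lists had adjusted p-values from 0.0542 to 0.956, and 1 of them, glycolysis and hypoxia genes (median -0.09), passed with the block (adjusted p = 0.0365, and 0.796 with an estimated correlation).

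Against mock, no footprint gene passed. Sp110 was at 2.91 (log2, SE 0.42, n = 4 per group, limma adjusted p = 0.112) and Esp24, of the exocrine gland peptide family, at 2.53 (SE 0.39, 0.112). Gm4858, named Tdpoz8 in RefSeq and so of the Tdpoz family, was at 2.35 (SE 0.39, 0.181). Those lower were Ndfip1, an adaptor of ubiquitin ligases (-0.61, SE 0.13), the DNA repair enzyme Mgmt (-0.72, SE 0.16) and A930015D03Rik (-1.03, SE 0.23), each with an adjusted p of 0.494. Of 39 genes of the 2-cell list 35 were above 0 (median 1.30, camera adjusted p = 8.94e-24, and 0.592 with an estimated correlation, range 1.11e-51 to 0.592), 0 passed over all genes and 13 adjusted over the list alone, and the score had an exact permutation p of 0.114. Trophoblast markers had a median of 0.29 (4 of 7 above 0, camera adjusted p = 0.514) and feeder markers of 0.13 (8 of 9 above 0, adjusted p = 0.264). By limma 0 of 10669 genes passed and 383 had an unadjusted p under 0.05, where chance gives 533. Leaving out inhibitor footprint 4 or mock footprint 4 gave 1 gene each.

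Another 4 lists passed in footprints against mock. Replication-dependent histones had a median of -0.14 (48 of 64 below 0, adjusted p = 0.00706, and 0.946 with an estimated correlation), ATF4 genes of -0.14 (18 of 22 below 0, 0.00706, and 0.508 with an estimated correlation), glycolysis and hypoxia genes of -0.16 (20 of 23 below 0, 0.00706, and 0.946 with an estimated correlation) and p53 targets of 0.18 (18 of 22 above 0, 0.00741, and 0.795 with an estimated correlation). The histone call was lost without inhibitor footprint 1 (-0.04, adjusted p = 0.724), inhibitor footprint 4 (-0.07, 0.205) and mock footprint 3 (-0.02, 0.948). The ATF4 adjusted p was 0.0820, 0.0928 and 0.118 without inhibitor footprints 1 and 2 and mock footprint 3, where the medians were -0.13, -0.17 and -0.19. That of glycolysis was 0.332, 0.0771 and 0.302 without inhibitor footprint 1 and mock footprints 1 and 4, with medians of -0.07, -0.16 and -0.07. That of p53 targets was 0.199, 0.0704 and 0.109 without inhibitor footprints 2 and 3 and mock footprint 3, with medians of 0.09, 0.15 and 0.10, and 0.0522 with no filter (median 0.17). Over the alternatives the adjusted p-values ranged from 3.08e-11 to 0.948, 0.000158 to 0.508, 2.59e-06 to 0.946 and 0.000262 to 0.795. The other 23 lists had adjusted p-values from 0.0824 to 0.958.

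Between GFP and mock footprints, the snoRNA Rnu73b was the 1 gene past the threshold. It was listed at 0 in all 4 mock libraries and at 1.81, 3.10, 3.8 and 5.18 scaled FPKM in the GFP libraries (n = 4 per group). As a snoRNA it is not translated, so its reads do not measure translation. The 2-cell list had a median of 0.03 (mean -0.01). Replication-dependent histones had a median of 0.07, with 49 of 64 members above 0 (camera adjusted p = 0.105). With the block their camera adjusted p was 0.00129, and 0.908 with an estimated correlation, although mock footprint numbers do not pair. They thus lay higher in GFP than in mock footprints, neither of which received the inhibitor. By limma 1 of 10669 genes passed (adjusted p = 0.000659, range over the alternatives 2.02e-05 to 0.0933), and without mock footprint 4 the count was 2. An unadjusted p under 0.05 was found for 49 genes, where chance gives 533, so this fit is cautious as well. Of 28 lists 0 passed (adjusted p from 0.105 to 0.974).

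Translational efficiency, footprint over mRNA, was compared to ask whether ribosome occupancy changed apart from mRNA level. For inhibitor against GFP no gene passed. The smallest p-values among genes higher were those of the snoRNA Snord83b (4.01, SE 1.22), Zbtb25 (1.14, SE 0.35) and the ribonuclease Rnase4 (1.04, SE 0.30), with n = 4 per group and assay. Among genes lower they were those of biotinidase, Btd (-0.81, SE 0.28), the 4-1BB ligand Tnfsf9 (-1.01, SE 0.31), whose mRNA stood at 1.19 and footprints at 0.18, and Rnu73b. The limma adjusted p was 1 for each. Snord83b and Rnu73b are snoRNAs, so their ratios, here and in the comparisons below, do not measure translation. The 2-cell list had a median of -0.12 (camera adjusted p = 0.262). Of 10497 genes 0 passed limma, and 75 had an unadjusted p under 0.05, where chance gives 525 if libraries are independent. This fit leaves out the pairs found above and is cautious. A count of 0 genes therefore does not show unchanged efficiency, here or in the comparisons below. With ratios of same-numbered libraries and the block, 0 passed and 229 had an unadjusted p under 0.05. The RNA and footprint numbers of these groups did not pair, however. RNA libraries 1 and 2 correlated best with footprints 2 and 1 in the inhibitor and in the GFP group. Of 28 lists 0 passed (adjusted p from 0.262 to 0.987), and with the block 1 did.

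For translational efficiency of inhibitor against mock, the germ cell gene Nanos3 (1.43, SE 0.48), Zbtb25 (1.11, SE 0.35) and Mapk1ip1 (0.92, SE 0.28) had the smallest p among genes higher, and Rprm (-0.99, SE 0.32), Rdh14 (-1.39, SE 0.39) and the readthrough Slc10a3-ubl4, listed at 0 in all 4 mock RNA libraries, among genes lower. None passed (n = 4 per group and assay, limma adjusted p = 1). The 2-cell list had a median of -0.10 (adjusted p = 0.523) and the replication-dependent histones of 0.15 (adjusted p = 0.274). Of 10497 genes 0 passed and 96 had an unadjusted p under 0.05.

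For translational efficiency of GFP against mock, 2310039H08Rik (1.34, SE 0.42), the coenzyme Q gene Coq9 (0.57, SE 0.21) and Rnu73b had the smallest p among genes higher, and Isoc1 (-0.76, SE 0.26), Nudt10 (-1.26, SE 0.48) and Snord83b (-3.27, SE 1.22) among genes lower. None passed (n = 4 per group and assay, limma adjusted p = 1). Cytosolic ribosomal proteins had a median of 0.06 (adjusted p = 0.0614). Of 10497 genes 0 passed and 39 had an unadjusted p under 0.05, and 0 of 28 lists passed.

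Changes in mRNA and in footprints were set side by side for inhibitor against GFP. Dcdc2c stood at 2.57 in mRNA and 3.11 in footprints, Tdpoz4 at 3.56 and 2.35, Sp110 at 2.35 and 2.85, Plet1 at 1.63 and 1.43, Bcas3 at -1.22 and -1.08, and Igfbp7 at -1.33 and -1.26. Of the 32 genes called in mRNA with the block, 30 were measured in footprints and 30 of these had the same sign there. The 27 rising ones had a median of 2.23 in mRNA and 1.92 in footprints. Across all 10497 genes, which are not independent replicates, Pearson's r was 0.44 and Spearman's rho 0.33, and r was 0.38 without the 2-cell list.

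**Figure D3:**
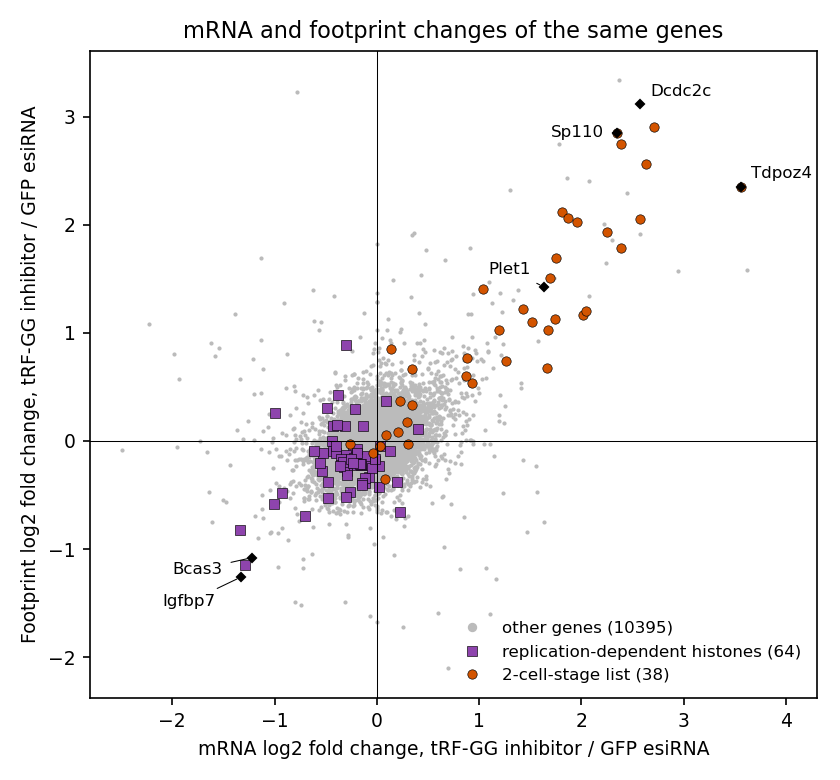
Log2 fold change of inhibitor over GFP libraries in mRNA (horizontal axis) and in ribosome footprints (vertical axis) for genes measured in both, with the 2-cell list (38 genes) and replication-dependent histones (64 genes) marked and 6 named genes shown as black diamonds. Tdpoz4 lies at 3.56 and 2.35 and Bcas3 at -1.22 and -1.08, and Pearson's r across all 10497 genes is 0.44.

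The comparisons with GFP and with mock RNA share the 4 inhibitor libraries. With the block, 26 genes were higher and 2 lower in both, where independent lists of these sizes would share 0.0716 and 0.000717. The fold changes of the 2 comparisons correlated across 12560 genes with r = 0.76 (covariance 0.0747), and simulated unchanged groups gave r = 0.50 (covariance 0.0368) and shared at most 1 call, a difference in covariance of 0.0379. The simulation kept the replicate block but drew each gene on its own. Its shared calls therefore give no measure for genes that vary together. With the inhibitor libraries divided between the comparisons in 6 ways, r ranged from 0.19 to 0.38 and the covariance from 0.0312 to 0.0581.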

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

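The tests of the 2-cell and histone patterns below were chosen only after the result was seen; the counts over other splits of the libraries were planned before. Of 187 groups of 4 libraries, 24 held a library whose gap to its nearest neighbour exceeded 0.83 of the group's range, where chance gives about 1 in 20 groups, or 9.3.

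The RNA libraries numbered 1 stood apart in their Rn45s share, at 18.1% in GFP (others 1.7% to 4.1%), 39.1% in mock (2.1% to 5.2%) and 62.7% in inhibitor libraries (2.2% to 5.3%). Their scaling factors were 0.449 in mock (others 1.25 to 1.37) and 0.170 in inhibitor RNA 1 (1.33 to 1.44), and inhibitor RNA 1 listed 6697 genes at 1 FPKM or more (others 11647 to 11884). Inhibitor footprint 3 had a relative depth of 20.4% (others 59.1% to 62.9%). The p53 target score of GFP RNA 2 was 0.265 (others -0.158 to -0.121), and the oxidative phosphorylation score of GFP footprint 3 was 0.255 (others -0.048 to -0.016).

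In mRNA, scaled FPKM far from the rest of the group were those of Tmem45a in mock RNA 4 (2.09), Taz in mock RNA 3 (11.1), Gm8994 (7.08) and Tdpoz5 (1.75) in GFP RNA 1, Sp110 in inhibitor RNA 4 (1.59, others 8.31 to 10.7), Plekha5 in inhibitor RNA 1 (1.47) and mock RNA 3 (5.19), AF067063 in mock RNA 1 (0.156, others 0) and Sbsn in mock RNA 4 (0.295, others 0). In footprints they were those of Sp110 in GFP footprint 2 (1.13), Plet1 in GFP footprint 4 (2.13), Rpl41 in inhibitor footprint 3 (1107, others 806 to 827), Ndufb8 in inhibitor footprint 1 (116), Esp24 in mock footprint 2 (0.658, others 0) and Gm4858 in mock footprint 1 (0.515).

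Genes of the 2-cell embryo were higher in inhibitor than in GFP RNA, with a median of 1.21. Without the RNA libraries numbered 1 the median was 1.09, and the score was higher in 3 of 3 remaining pairs, which argues against those libraries as the whole cause. The 6 members with no near-identical copy by general knowledge had a median of 1.04, from 0.08 for Calcoco2 to 1.70 for Arg2, but they were chosen after their values were seen and copies were not compared by sequence, so that reads shared between copies cannot be told apart from a change of each gene. Against the spread between libraries, the score was higher in 4 of 4 pairs, by 1.24 ± 0.46 (SD), and 13 members rose over all genes in the paired fit. There limma's fry gave the list an adjusted p of 0.0263. But the fry adjusted p was 0.114, 0.0850 and 0.138 without inhibitor RNA 1, 2 and 3 and 0.124, 0.0739 and 0.124 without GFP RNA 1, 2 and 3 (range leaving out 1 library 0.000348 to 0.138, unadjusted 1.24e-05 to 0.00528). The exact permutation p was 0.0571 unpaired, and 0.125, the smallest possible, over the sign changes of the pairs. With 4 libraries per group this spread cannot be told apart. Whether the response belongs to tRF-GG or to LNA chemistry cannot be told apart, because no group received another LNA oligonucleotide; GFP against mock, which compares groups without LNA, gave a median of 0.0209.

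Replication-dependent histones were lower in inhibitor than in GFP RNA, with a median of -0.26. Without the RNA libraries numbered 1 the median was -0.0442, so that the mRNA difference may come from those libraries, which hold the largest Rn45s shares. Against mock mRNA without them it was -0.15, with 44 of 64 members below 0 (camera adjusted p = 0.160). Footprints, which include none of these libraries, gave -0.21 against GFP with 52 of 64 below 0, but -0.07 without GFP footprint 3. Against mock footprints the median was -0.14, and GFP footprints lay above mock, with a median of 0.07 and 49 of 64 members above 0. The spread between libraries may account for the mRNA difference as well. Its score was lower in 3 of 4 pairs, with a mean difference of -0.30 ± 0.46 (SD). The exact permutation p was 0.171 unpaired, and 0.375 over the sign changes of the pairs. Genes of DNA replication had a median of 0.0154 (29 genes, mean -0.03, quartiles -0.0669 and 0.0728), and a smaller share of cells in S phase cannot be told apart from these values, since they go both ways and lie close to 0. An effect of the inhibitor itself remains open and was not tested apart from these.

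For the counts of genes in mRNA, 2 of the 35 splits of the 8 libraries gave as many as the 2 genes of inhibitor against GFP. The highest other split, which put libraries 1 and 2 of both groups together, gave 670, many times the real count, and points to a structure that follows the replicate numbers. For inhibitor against mock 1 of 35 splits, the real one, gave 3 genes and the highest other gave 1, so chance can be excluded for that count only if the libraries are taken as unpaired, and leaving out inhibitor RNA 1 or 3 or any mock library gave 0 genes, with the folds of the 3 genes at 2.03 to 2.30 (Sbsn), 2.07 to 2.38 (AF067063) and -1.30 to -1.16 (Bcas3). Among the 8 splits that part all pairs, with the block, the real splits gave 32 and 34 genes and the highest others 0 (1 split each as large), but 8 splits are too few for a share under 0.05. For GFP against mock the real count was 0, which all 35 splits reach whatever the data, so the splits say nothing of it (2 at the highest).

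For footprints, 2 of 35 splits gave as many as the 1 gene of inhibitor against GFP (highest other 2), and 3 of 35 gave as many as the 1 gene of GFP against mock. Chance is not excluded for these. The highest other split of GFP against mock gave 941 genes and put GFP and mock libraries 1 and 2 together. With the block, the real split of inhibitor against GFP gave 8 genes and the highest other of 8 splits gave 0 (1 as large), again too few splits. The real count was 0 for footprints of inhibitor against mock (highest other 1) and for translational efficiency, where 100 splits were drawn for each comparison (highest 170, 1 and 480), and splits cannot test a count of 0.

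For counts of passing lists, chance is not excluded over all 35 splits. In mRNA, 31 of 35 splits gave at least the 2 lists of inhibitor against GFP (highest 12) and 25 at least the 5 of inhibitor against mock (highest 13), with a median of 7 lists over the splits. In footprints, 24 of 35 gave at least the 7 of inhibitor against GFP (highest 17) and 26 at least the 5 of inhibitor against mock (highest 16), with a median of 8. Among the 8 splits that part all pairs the highest others gave 5 and 6 lists in mRNA against GFP and mock, and 5 in footprints against GFP, below the real 7, but 8 splits are too few for a share under 0.05. Where the real count was 0, in GFP against mock mRNA and footprints (highest others 13 and 15) and in translational efficiency (17, 16 and 17), splits cannot test it.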

How the results depend on the processing

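Settings that leave out the RNA libraries numbered 1, or combine the block with the fit of 2 groups or with an estimated correlation were chosen only after the result was seen. For inhibitor against GFP mRNA (2 genes), the count was 1 with a pseudocount of 0.1, 0 with no filter on low values, 1 at a mean FPKM of at least 5, 14 with FPKM as deposited (14 higher, 0 lower), 1 with quantile normalization (0 higher, 1 lower) and 0 with only the 2 groups compared. It was 32 with the replicate block, 0 without the RNA libraries numbered 1, 9 without them and with the block, and 18 with the block and only the 2 groups. For inhibitor against mock mRNA (3 genes), it was 1 at a mean FPKM of at least 5, 18 with FPKM as deposited (17 higher, 1 lower), 0 with only the 2 groups compared, 34 with the replicate block, 14 with the block and without libraries numbered 1, and 15 with the block and only the 2 groups. Without the libraries numbered 1 it was 3, of which 0 were among the 3.

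For inhibitor against GFP footprints (1 gene), the count was 3 with no filter on low values, 0 at a mean FPKM of at least 5, 4 with FPKM as deposited, 8 with the replicate block, and 45 with the block and only the 2 groups. Against mock (0 genes) it was 1 with no filter, 3 with FPKM as deposited, 2 with the replicate block and 1 with the block and only the 2 groups. For GFP against mock footprints (1 gene), it was 0 at a mean FPKM of at least 5, 2 with only the 2 groups compared, and 0 with the block and only the 2 groups. Translational efficiency (0 genes) gave 1 with FPKM as deposited for inhibitor against GFP and 1 for GFP against mock.

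Counts of lists with the replicate block were 6 (inhibitor against GFP), 8 (inhibitor against mock) and 2 (GFP against mock) in mRNA, 4 for GFP against mock footprints, and 1 and 1 for translational efficiency of the inhibitor against GFP and against mock. With an estimated correlation, block or not, they were 0 in mRNA and footprints of the inhibitor against either control. FPKM as deposited gave 1 list for GFP against mock footprints and 1 and 3 for translational efficiency of the inhibitor. Quantile normalization turned the median of cytosolic ribosomal proteins to 0.0188 in mRNA against mock and to 0.0221 in footprints against GFP. Leaving out 1 library, the latter ranged from -0.154 (without inhibitor footprint 3) to 0.0229 (without GFP footprint 3), that of oxidative phosphorylation in footprints against GFP from -0.119 to 0.00676 (same libraries), and that of histones in footprints against mock from -0.301 (without inhibitor footprint 3) to -0.0184 (without mock footprint 3), where camera set the list higher than the remaining genes.

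Leaving out 1 library at a time gave 0 to 15 genes for inhibitor against GFP mRNA, 0 to 18 against mock, 1 to 3 for inhibitor against GFP footprints, 0 to 1 against mock, and 1 to 2 for GFP against mock footprints. The cause was not tested for any of these changes, except that fewer genes are tested at 5 FPKM, where 50 results for named genes were not tested. With FPKM as deposited the median of all genes was -0.39, -0.19 and 0.21 in the 3 mRNA comparisons (-0.01, -0.01 and 0.00 scaled), and 0.39, 0.20 and -0.20 in translational efficiency (0.03, 0.01 and -0.02 scaled). Footprint libraries of the mock group were not paired by number: inhibitor and mock correlated from -0.19 to 0.64, GFP and mock from 0.09 to 0.87, with 2 of 4 best with their own number in each. Mock footprints 1 and 2 correlated best with number 2 (0.78 in GFP, 0.58 in inhibitor) and number 1 (0.85 and 0.8), a hint from the data and not the design. Footprint and RNA libraries of one number correlated from -0.24 to 0.44 in GFP (2 of 4 best) and from 0 to 0.21 in inhibitor groups (1 of 4), and from 0.17 to 0.38 in mock (4 of 4). RNA libraries 1 and 2 correlated best with footprints 2 and 1 in GFP (0.26 and 0.54) and in inhibitor groups (0.31 and 0.42). The numbers that differ may therefore be those of GFP and inhibitor footprints 1 and 2 rather than those of mock. No numbers were exchanged here. Beyond single libraries, of results for single genes 586 kept side and direction, 67 passed and 21 no longer did; of lists 147 kept it, 36 no longer passed and 2 turned direction. In paired comparisons the block ended no call and changed no others than those given here or beside the result. Depth limits genes near 1 FPKM in mock RNA 3, at 7.2% of the deepest library. Relative depth includes reads of Rn45s. Inhibitor RNA 1 had a relative depth of 68.9%, but 62.7% Rn45s and a scaling factor of 0.170. Low values of that library are therefore limited as well.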

Other observations

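Gene span was not among the 29 lists fixed before the data were examined, and the long genes named below were picked for their change in these libraries. The tests of gene span below were planned before their own results were seen, except the one that compares GFP with mock and those over pairs. Of the 29 genes higher in inhibitor than GFP mRNA in the paired fit, 13 belonged to the 2-cell list, where 0.109 would by chance (Fisher's exact test, p = 2.97e-25), and of the 31 higher than mock 14 did (0.116 by chance, p = 3.14e-27). This test takes genes as independent, which members of families of similar genes are not. In the same paired fit with an estimated correlation, the list had camera adjusted p-values of 0.115 against GFP and 0.158 against mock (ranges over the alternatives 1.36e-122 to 0.356 and 1.07e-114 to 0.491). The other 16 of the 29 included Gm4858, named Tdpoz8 in RefSeq and so of the Tdpoz family of the list. Gm10696 lies near Tdpoz5 on chromosome 3, and B020031M17Rik near AF067063 on chromosome 13. The 16 are therefore not all apart from the listed families. Further ones were Abt1, an activator of basal transcription (2.07, 73.1 ± 26.7 against 16.4 ± 5.38 scaled FPKM, SD, n = 4), Dcdc2c, Plet1, and the epithelial transcription factor Grhl2 (0.99, 8.14 ± 3.17 against 3.66 ± 1.69). Krtap4-13, a hair keratin-associated protein, was listed at 0 in all 4 GFP libraries. Whether such genes vary with the 2-cell list among the 8 control RNA libraries was not tested, since these form 4 pairs and the pair numbered 1 stood apart, with list scores of 0.30 and 0.53 where the other 6 lay between -0.90 and -0.42.

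Genes spanning over 200 kb were lower in inhibitor mRNA, with a median of -0.19 over 444 genes against -0.01 over 12056 others, and 77.7% against 51.4% below 0. Against mock these medians were -0.19 and -0.00, and for GFP against mock 0.01 and 0.00. Among them, Bcas3 spans 472.9 kb, Ptprg 688.6 kb (chromosome 14, 11553440 to 12242041) and Trappc9, lower in inhibitor footprints with the block, 471.6 kb (chromosome 15, 72589620 to 73061238). In footprints the difference between long and other genes was -0.09 against GFP and -0.12 against mock, and in translational efficiency 0.13 and 0.08. For GFP against mock footprints it was -0.02. Over all genes, Spearman's rho of fold change with span was -0.16 and -0.13 in mRNA against GFP and mock, and 0.02 for GFP against mock. In footprints these were -0.01, -0.08 and -0.12. Over all footprint genes, the trend with span was thus not particular to the inhibitor. The score per library, long minus other genes, was -0.13 ± 0.02 (SD, n = 4) in inhibitor and 0.07 ± 0.10 in GFP RNA, lower in 4 of 4 pairs, with differences from -0.29 to -0.11. In footprints it was lower than in GFP libraries in 4 of 4 pairs, with differences from -0.16 to -0.03 and an exact permutation p of 0.143 unpaired and 0.125, the smallest possible, over the sign changes of the pairs. Against mock, whose footprint numbers do not pair, it was -0.07 ± 0.05 against 0.04 ± 0.09 (SD, n = 4, exact permutation p = 0.0857), lower in 4 of 4 comparisons of equal number, with differences from -0.25 to -0.06.

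A candidate explanation is that blocking tRF-GG lowers the mRNA of genes with a long span on the genome. Span includes introns, and the length of the mRNA itself was not examined. The alternatives named here were looked at in mRNA against GFP, and others were not tested. Without the RNA libraries numbered 1 the difference was -0.184, which argues against those libraries as the cause. Against matched sets of genes of equal mean level the long genes lay at -0.193, with the medians of 1000 sets between -0.0369 and 0.0444, which argues against expression level. The exact permutation p of the score was 0.0286, the smallest that 4 against 4 libraries can give, and 0.0857 adjusted over 6 comparisons, which does not pass and could not for a single comparison at that p. That test takes the libraries as unpaired. Over the pairs the differences were -0.20 ± 0.08 (SD), lower in 4 of 4, with an exact p of 0.125 over the sign changes, the smallest possible. With 4 libraries per group, the spread between libraries cannot be told apart. An effect of any LNA oligonucleotide on genes of long span cannot be told apart, as no group received another one. GFP against mock gave a difference of 0.00201.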
